A study of Mus musculus with 9 samples.

How the data were processed

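RNA from the retinal pigment epithelium (RPE) of wild-type mice was measured by bulk RNA sequencing in 9 libraries. Per the labels, 3 libraries came from young controls aged 9 months, 3 from aged controls aged 24 months, and 3 from mice aged 24 months that had received vutiglabridin, a synthetic small molecule derived from glabridin, for 6 months. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a kit for stranded total RNA (TruSeq Stranded Total RNA Gold). The labels give neither the sex of the animals nor a sequencing batch, and they do not say that the libraries come from separate animals; the p-values measure the spread between these samples only.

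Per the submitters' processing notes, the authors aligned reads with Bowtie2 2.3.4.1, counted them per gene with featureCounts 1.6.0 and used DESeq2 (no version given), with GRCm38 as the genome build. The deposited table holds 1 raw count and 1 FPKM value per gene and library for 40202 genes, per the file headers. The deposited FPKM equals the count divided by the span of the gene and by the sum of the library's counts, within a relative tolerance of 1e-06. The deposited length equals the whole span of the gene, introns included, for all 40200 genes with 1 span. A read in a region where genes overlap appears to have been counted for each of them whatever its strand. Among nested pairs on opposite strands, the inner gene's count was at or under the outer gene's count in all libraries for 1430 of 1448 pairs, and for 868 of 868 pairs on the same strand. The exceptions on opposite strands were not explained, and this sign alone does not prove the rule. Since 17809 genes overlap another gene, values of overlapping and antisense partners cannot be told apart. Coordinates are the deposited ones. The notes name GRCm38, but the table's chromosome versions are those of GRCm39, and 769 of 38629 nuclear genes matched by symbol to a GRCm38.p6 gene table have the same start there; no coordinate was converted. The deposited gene biotype column was not used, because its entries are out of step with the gene symbols.

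Raw counts were the only values tested. Genes were kept by edgeR's filterByExpr with the 3 groups as design, which left 25273 genes. Counts were scaled by trimmed mean of M values (TMM) and fitted for all 9 libraries together, without covariates, by the quasi-likelihood method of edgeR 4.0.16 with robust estimation, in R 4.3.3. The contrasts were aged control minus young control, treated aged minus aged control, and treated aged minus young control. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Unless another tool is named, adjusted p-values of genes come from this test. The standard error (SE) of a log2 fold change was taken from the fold change and its F statistic. Levels are CPM computed here from the deposited counts and the TMM-scaled library sizes, as mean and standard deviation (SD) over 3 libraries. Total counts per library ranged from 44196290 to 56797891.

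Fixed gene lists, 45 in number, covered RPE functions, mitochondria and metabolism, senescence, immunity, stress responses and the other cell types that a dissected RPE sample could hold; 890 of their 893 symbols were found in the table. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and an inter-gene correlation preset at 0.01, and p-values were adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction, were run beside it. List medians and means are of fitted log2 fold changes. The groups, the tests, the lists, the rule for named genes and most alternatives were set before the data were examined. That rule took, per comparison, the 10 largest rises and the 10 largest falls among called genes with a mean CPM of at least 1 and no overlap between the groups, up to 4 members with the smallest p of each list described, 10 genes of prior interest, and the 5 genes with the smallest treatment p among those called in opposite directions with age and with treatment. Not all genes it took are named in the text, and 3 were left out of the results for named genes and are not reported here. Genes and 4 further lists chosen after the values were seen are said to be so where they appear.

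Alternatives, set out in the closing section, were other size factors (relative log expression, upper quartile, total counts), DESeq2 1.42.0, limma-voom with quality weights, no filter or a filter of at least 1 CPM in 3 libraries, other thresholds, only the 2 groups compared, the replicate number as a block, the rod list as a covariate, other cell types' genes or abundant and mitochondrial genes left out, and each library left out in turn. Added after the data were seen were a fit of 7 libraries without both that stand apart, only genes that overlap no other gene, and covariates for haemoglobin and for stratified epithelium. For genes called in opposite directions, counts were simulated in 25 draws with the fitted age effects and no treatment effect, and in 25 draws with no effects.

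The fit was tested on simulated counts with known changes. At changes of 1.5-fold, 2-fold and 4-fold it recovered 7.46%, 60.6% and 81.5% of changed genes for age (24968 genes), 17.9%, 50.7% and 80% for treatment (24914 genes), and 7.69%, 43.1% and 83.3% for treated aged against young (24948 genes). Of the unchanged genes, 9 of 24770 were called for age, 12 of 24715 for treatment and 7 of 24752 for treated aged against young. The changed genes recovered at the 3 sizes were 5, 40 and 53 for age and 12, 34 and 52 for treatment. For treated aged against young they were 5, 28 and 55. False calls were thus a share above 0.05 of the calls in each comparison. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.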

Results

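RNA of the RPE, the pigmented cell layer that recycles the visual pigment chromophore and clears shed photoreceptor outer segments, was sequenced from young mice, aged mice, and aged mice given vutiglabridin for 6 months, with 3 libraries per group. Total counts were 44196290, 45143840 and 56797891 in the young libraries. They were 55713593, 50458875 and 48715263 in the aged control libraries, and 45534152, 47368767 and 53239652 in the treated libraries. Between 28873 and 32523 genes had a count in each library, and 0.889% to 1.319% of counts lay in mitochondrial genes. Levels below are CPM as mean ± SD, and log2 fold changes are given ± SE, with n = 3 per group.

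The RPE genes Rpe65, the retinoid isomerase, and Ttr, the retinol carrier transthyretin, stood at 2980 ± 144 and 3000 ± 478 CPM in young RPE. Markers of other tissue were present too. In aged controls 17 of 17 endothelium, 16 of 16 fibroblast and 17 of 17 skeletal muscle markers had a mean of at least 1 CPM. So did 24 of 25 rod markers and 19 of 20 macrophage and microglia markers. Below, RPE names the dissected sample, and differences cannot be assigned to RPE cells. Some libraries stood apart from the rest of their group. Treated replicate 2 lay at 2.627 on the first dimension of a multidimensional scaling plot, the highest value of the 9 libraries. In this library 0.491% of counts were haemoglobin transcripts, against 0.004% to 0.059% elsewhere, and Krt5, a keratin of stratified epithelium, reached 62.8 CPM. Its level of Trpm3, an abundant cation channel gene, was 2090 CPM, against 5180 and 5570 CPM in the other treated libraries. Young replicate 1 lay at 2.001 on the second dimension, and 0.153% of its counts were the mitochondrial ribosomal RNA mt-Rnr2, against 0.427% to 0.545% elsewhere. Treated replicate 3 had the highest rod gene levels, with a list median 1.13 above the mean of the libraries on the log2 scale. Krt5, Trpm3 and mt-Rnr2 were chosen after their values were seen.

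**Figure D1:**
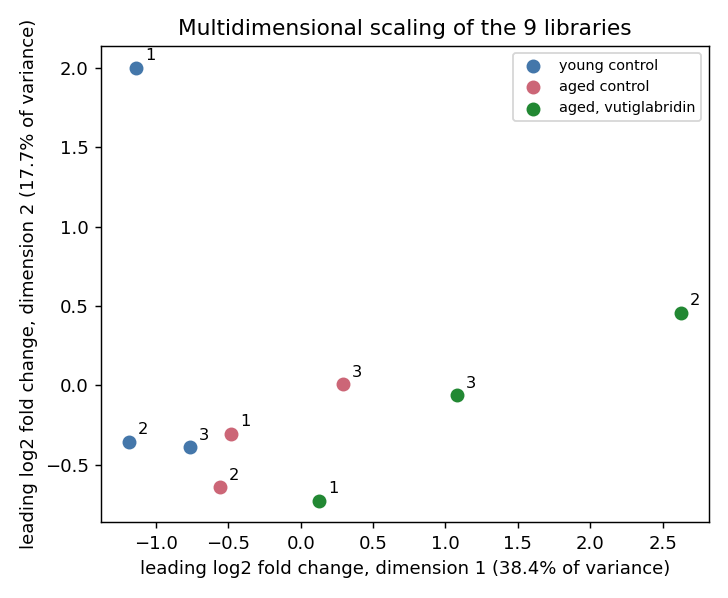
Multidimensional scaling of the 9 libraries by log2 CPM, with the first dimension (38.4% of the variance) on the x axis and the second (17.7%) on the y axis; each point is a library, coloured by group. Treated replicate 2 lies at 2.627 on the first dimension and young replicate 1 at 2.001 on the second.

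The first comparison asked how the RPE of aged mice differs from that of young mice. Genes of antigen presentation were higher in the aged samples: 18 of the 20 measured members rose, and the other 2 did not pass the test. Nlrc5, the transactivator of MHC class I genes, stood at 18.3 ± 2.19 CPM in young and 64.0 ± 6.45 CPM in aged RPE (log2 fold change 1.81 ± 0.13, adjusted p = 0.000566). Tap2, a subunit of the peptide transporter that loads MHC class I, rose from 23.8 ± 1.03 to 38.4 ± 1.71 CPM. Among the 10 largest rises of called genes with a mean CPM of at least 1 and no overlap between the groups were Gbp4 (2.68 ± 0.29, adjusted p = 0.00498) and Igtp (2.17 ± 0.23, adjusted p = 0.00358), interferon-inducible GTPases, and Acod1, the itaconate-forming enzyme of activated macrophages (4.18 ± 0.43, adjusted p = 0.00303). The Gbp4 level went from 11.5 ± 0.87 to 73.5 ± 17.5 CPM. H2-Q7 and H2-Q9, MHC class Ib genes with 2.22 and 2.28, are close copies of each other, so the share of reads from each is uncertain. The antigen presentation list had a median log2 fold change of 1.18 (adjusted p = 1.24e-29, and adjusted p = 0.084 with an estimated correlation); 20 members passed when adjusted over the list alone. Of 26 measured interferon-stimulated genes 4 rose, and 7 when adjusted over the list alone (median 0.50, adjusted p = 2.7e-09, and adjusted p = 0.58 with an estimated correlation). With 1 library left out, the count of risen antigen presentation genes ranged from 8 to 19, with 9, 8 and 11 without young control 3, aged control 1 and aged control 2. That of interferon-stimulated genes ranged from 1 to 6, with 2 and 1 without young control 1 and 3 and 1 each without aged control 1 and 2. In the deposited coordinates Nlrc5 lies on chromosome 8 from 95160963 to 95253900, Gbp4 on chromosome 5 from 105263633 to 105287452 and Igtp on chromosome 11 from 58090382 to 58098418.

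Some markers of immune cells were also higher in aged RPE. Cd3e, a subunit of the T cell receptor complex, rose from 0.161 ± 0.0402 to 0.853 ± 0.0825 CPM (2.40 ± 0.31, adjusted p = 0.00609). Tyrobp, a signalling adaptor of myeloid cells, rose from 24.1 ± 4.96 to 53.0 ± 0.685 CPM (1.14 ± 0.15, adjusted p = 0.00686). Of 17 measured lymphocyte and plasma cell markers 6 rose (11 adjusted over the list alone), with a median of 1.65 (adjusted p = 6.91e-15, and adjusted p = 0.053 with an estimated correlation). Of 20 macrophage and microglia markers 8 rose (13 adjusted over the list alone), with a median of 0.77 (adjusted p = 2.97e-11, and adjusted p = 0.40 with an estimated correlation). Of 40 senescence-associated secretory factors 3 rose (11 adjusted over the list alone), among them the membrane metalloproteinase gene Mmp14 and the chemokine gene Cxcl16 (0.77 ± 0.11 and 0.96 ± 0.14). Both lost their call without aged control 1, with adjusted p of 0.0536 and 0.0529. The secretory factor list had a median of 0.49 (adjusted p = 9.07e-08, and adjusted p = 0.40 with an estimated correlation). The complement list, with 2 of 24 members risen (8 adjusted over the list alone), had a median of 0.26 (adjusted p = 0.00519, and adjusted p = 0.59 with an estimated correlation). It lost its call without aged control 2 (median 0.17, adjusted p = 0.071). The NF-kB and acute inflammation list, with 1 of 22 risen (4 adjusted over the list alone), had a median of 0.32 (adjusted p = 0.0024, and adjusted p = 0.63 with an estimated correlation). With 1 library left out, the count of risen macrophage and microglia markers ranged from 1 to 11, with 1 and 2 without young control 1 and 3, and 1, 3 and 2 without aged control 1, 2 and 3. That of lymphocyte markers ranged from 1 to 7, with 3 without young control 1, and 1, 3 and 3 without aged control 1, 2 and 3. The secretory factor count ranged from 0 without aged control 1 to 8 without treated replicate 2, the complement count from 0 without each aged control to 6 without treated replicate 2, and the NF-kB count from 0 to 3.

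Some pigment and vessel genes were lower. Mme, which encodes the membrane peptidase neprilysin, fell from 19.5 ± 2.01 to 8.38 ± 0.54 CPM (-1.22 ± 0.12, adjusted p = 0.00303). Thbd, the endothelial anticoagulant thrombomodulin, fell from 83.8 ± 4.1 to 44.3 ± 3.77 CPM (-0.92 ± 0.11, adjusted p = 0.00498). Of 20 melanogenesis and melanosome genes 2 fell and 1 rose (9 and 1 adjusted over the list alone), with a median of -0.29 (adjusted p = 0.000588, and adjusted p = 0.59 with an estimated correlation). Slc45a2, a melanosomal transporter gene, went from 187 ± 1.82 to 128 ± 3.3 CPM (-0.55 ± 0.08, adjusted p = 0.00833). The call was lost without aged control 1 or 3 (adjusted p up to 0.0649). The count of fallen melanogenesis genes ranged from 0 without aged control 1 or 3 to 5 without treated replicate 2. The choroidal melanocyte list, with 1 of 9 members fallen (2 adjusted over the list alone), had a median of -0.23 (adjusted p = 0.00433, and adjusted p = 0.58 with an estimated correlation). Its count of 1 was 0 by edgeR without aged control 1 or 3. The endothelium list had a median of -0.26 and 15 of its 17 members below 0 (adjusted p = 3.94e-05, and adjusted p = 0.40 with an estimated correlation). Of these members 5 fell when adjusted over the list alone, and over all genes the angiopoietin receptor genes Tie1 and Tek had adjusted p of 0.0738 and 0.0976. The RPE identity list had a median of -0.19 (adjusted p = 0.00519, and adjusted p = 0.63 with an estimated correlation). Rpe65, at -0.39 ± 0.13 (adjusted p = 0.249), was its member of smallest p. Skeletal muscle markers, which a dissected RPE sample can hold from eye muscle, had a median of 0.89 (adjusted p = 0.000238, and adjusted p = 0.63 with an estimated correlation). Inner retinal neuron markers had a median of 0.27 (adjusted p = 0.0184, and adjusted p = 0.61 with an estimated correlation). The skeletal muscle call was lost without young control 2 (median 0.58, adjusted p = 0.071). Without young control 2 the median of the inner retinal neuron list was 0.73.

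The genes of prior interest did not pass the test with age. C3, the central complement component, stood at 15.7 ± 3.59 CPM in young and 44.9 ± 2.67 CPM in aged samples (1.51 ± 0.33, adjusted p = 0.0649). The senescence marker Cdkn1a was at 2.39 ± 0.219 and 3.94 ± 0.645 CPM (adjusted p = 0.481). Cdkn2a had 1 to 7 counts per young library and 5 to 11 per aged control library, too few to be tested. Pon2, a paraoxonase of mitochondria and endoplasmic reticulum, differed by -0.05 ± 0.08 (adjusted p = 0.898), and Glb1, the senescence-associated beta-galactosidase gene, by 0.10 ± 0.11 (adjusted p = 0.815). Ppargc1a, Hmox1 and Gfap had adjusted p of 0.604, 0.395 and 0.832. The smaller list calls followed. Cholesterol synthesis and lipid handling had a median of 0.18 (adjusted p = 0.00446, and adjusted p = 0.58 with an estimated correlation), with 3 of 31 members risen when adjusted over the list alone. Epithelial-mesenchymal transition had 1 of 22 risen (4 adjusted over the list alone) and a median of 0.17 (adjusted p = 0.0248, and adjusted p = 0.59 with an estimated correlation). Autophagy and lysosome genes had a median of 0.06 (adjusted p = 0.0431, and adjusted p = 0.73 with an estimated correlation). Ciliary body and iris markers had a median of -0.21, with 1 of 10 fallen adjusted over the list alone (adjusted p = 0.0431, and adjusted p = 0.40 with an estimated correlation). Nuclear genes of OXPHOS complex I had a median of -0.08 (adjusted p = 0.0431, and adjusted p = 0.88 with an estimated correlation). The transition call was lost without young control 2 or 3 or aged control 1 (adjusted p up to 0.0711). The autophagy call was lost without young control 3, aged control 1 or 2, or treated replicate 2 (adjusted p up to 0.238). The ciliary body call was lost without young control 1 or 2 or aged control 2 (adjusted p up to 0.141), with medians from -0.39 to -0.11 over the libraries left out. The complex I call was lost without young control 1, aged control 1 or 3, or treated replicate 2 or 3 (adjusted p up to 0.79), with medians from -0.16 to 0.02. The other 27 lists had adjusted p from 0.0547 to 0.969.

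In all, 424 of 25273 genes were called with age in edgeR's quasi-likelihood test, 373 higher and 51 lower. An unadjusted p under 0.05 was seen for 2945 genes. The count was 201 and 110 without young control 1 and 3, 73, 148 and 132 without aged control 1, 2 and 3, and 688 and 653 without treated replicate 2 and 3. Of the 49 named genes called, 29, 38 and 23 kept their call without young control 1, 2 and 3, and 17, 27 and 28 without aged control 1, 2 and 3.

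The second comparison asked what differs in aged RPE after vutiglabridin. Many of the antigen presentation genes and some of the interferon-inducible genes that were higher with age were lower in treated than in aged control samples: 16 of the 20 measured antigen presentation genes fell, and the other 4 did not pass the test. Ciita, the master regulator of MHC class II genes, fell from 34.9 ± 3.37 to 13.9 ± 1.45 CPM (-1.33 ± 0.13, adjusted p = 0.00297). Igtp fell from 59.9 ± 14.5 to 14.4 ± 3.57 CPM (-2.05 ± 0.23, adjusted p = 0.00468). Gbp7, another interferon-inducible GTPase, fell from 87.7 ± 15.7 to 36.5 ± 3.43 CPM (-1.27 ± 0.14, adjusted p = 0.00409). Gbp4 fell from 73.5 ± 17.5 to 13.2 ± 5.73 CPM, a call that aged control 2 decides (adjusted p = 0.0072, and 0.0531 without that library). The antigen presentation list had a median of -0.93 (adjusted p = 1.54e-15, and adjusted p = 0.36 with an estimated correlation), with 19 members passing when adjusted over the list alone. Of 26 interferon-stimulated genes 4 fell, and 5 when adjusted over the list alone (median -0.34, adjusted p = 2.58e-05, and adjusted p = 0.75 with an estimated correlation). Without treated replicate 1 the median was -0.54. The count of fallen antigen presentation genes was 2, 1 and 5 without aged control 1, 2 and 3, and 11 to 18 without another library, while the list median stayed between -1.09 and -0.82. That of interferon-stimulated genes was 2 without aged control 1 or 2 and 3 to 6 without another library. A list of 16 interferon-gamma-inducible GTPases, drawn up after these genes had been seen, had 15 members higher with age and 15 lower with treatment, and 9 to 16 and 7 to 15 with 1 library left out.

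Some lymphocyte genes were lower as well. Of 17 lymphocyte and plasma cell markers 4 fell, also when adjusted over the list alone. They were the immunoglobulin heavy chain gene Ighm (8.21 ± 3.21 to 2.22 ± 0.914 CPM), the B cell receptor subunit Cd79a (0.727 ± 0.0118 to 0.256 ± 0.0552 CPM), the B cell surface gene Ms4a1 and the cytotoxic granule protease gene Gzma. The list had a median of -0.20 (adjusted p = 0.0118, and adjusted p = 0.65 with an estimated correlation). Its median ranged from -0.44 to -0.04 over the libraries left out, the extremes being those without treated replicate 3 and treated replicate 2. It was -0.34 and -0.38 without aged control 2 and 3. Ighm lost its call without aged control 1 or 2 (adjusted p up to 0.112). Cd79a, Ms4a1 and Gzma, with group means of at most 1.02 CPM, lost theirs without any 1 of the aged controls, young control 2 or treated replicate 1 or 2, and Ms4a1 and Gzma also without young control 3 (adjusted p up to 0.15, 0.163 and 0.175). The count of 4 fallen markers was 2 without young control 3 and at most 1 without any 1 of the aged controls, young control 2 or treated replicate 1 or 2. Cd3e stood at 0.853 ± 0.0825 CPM in aged control and 0.875 ± 0.109 CPM in treated samples. The macrophage and microglia list had a median of -0.08 (adjusted p = 0.425), with 1 of 20 members fallen (2 fallen and 1 risen when adjusted over the list alone).

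**Figure D2:**
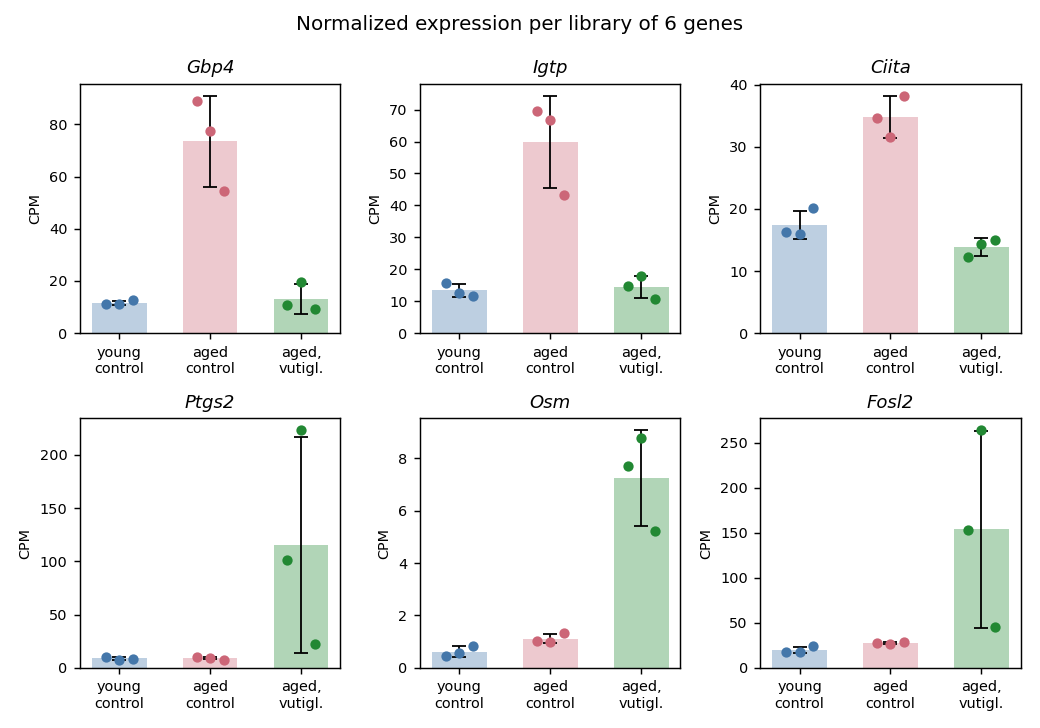
CPM of 6 genes in the 9 libraries; bars are group means, error bars SD and points single libraries (n = 3 per group). Gbp4, Igtp and Ciita are higher in aged controls than in both other groups, for example Gbp4 at 11.5, 73.5 and 13.2 CPM, while Ptgs2, Osm and Fosl2 are highest in the treated group, with wide spread between its libraries.

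Some inflammatory mediators and immediate early genes were higher in the treated samples. Osm, the gene of the cytokine oncostatin M, rose from 1.12 ± 0.174 to 7.24 ± 1.83 CPM (2.69 ± 0.27, adjusted p = 0.00393). Among called genes with a mean CPM of at least 1 and no overlap between the groups, the largest rise was that of Ptgs2, the inducible cyclooxygenase gene, from 8.89 ± 1.1 to 115 ± 101 CPM (3.70 ± 0.74, adjusted p = 0.0399). Its call was kept in 2 of the 9 fits that leave out 1 library, without young control 1 or treated replicate 3, and its adjusted p reached 0.175. Of 19 immediate early genes, which respond within minutes to stimuli, 3 rose, and 16 when adjusted over the list alone (median 1.81, adjusted p = 2.13e-07, and adjusted p = 0.71 with an estimated correlation). Fosl2, an AP-1 subunit gene and 1 of those 3, had a log2 fold change of 2.48 ± 0.54 and kept its call only without treated replicate 3 among those fits (adjusted p up to 0.19). Of 22 NF-kB and acute inflammation genes 5 rose and 1, the interleukin gene Il18, fell (17 and 2 adjusted over the list alone), with a median of 0.70 (adjusted p = 1.25e-05, and adjusted p = 0.71 with an estimated correlation). Il18 kept its call in 2 of those fits, without young control 1 or treated replicate 3 (adjusted p up to 0.156). The count of risen immediate early genes was 14 without treated replicate 3, 4 without treated replicate 2, 1 and 2 without young control 1 and 3, and 0 by edgeR without young control 2, treated replicate 1 or any 1 of the aged controls. Dusp1 and Klf4, the other named members, kept their call in 2 and 3 of the 9 fits (adjusted p up to 0.186 and 0.188). The count of risen NF-kB and acute inflammation genes was 17 without treated replicate 3, 4 without young control 1, 1 without young control 3 or treated replicate 1 or 2, and 0 by edgeR without young control 2 or any 1 of the aged controls. Without treated replicate 2, the library with the most haemoglobin and keratin transcripts, the medians of these lists were 0.90 and 0.43. The erythrocyte list had a median of 3.27 (adjusted p = 0.131) in this comparison.

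A minority of the secretory, matrix and mesenchymal genes rose too. Ccn2, the gene of connective tissue growth factor, rose from 301 ± 22.8 to 732 ± 136 CPM (1.28 ± 0.13, adjusted p = 0.00409). Fn1, the fibronectin gene, rose from 203 ± 3.85 to 476 ± 116 CPM (1.23 ± 0.16, adjusted p = 0.0072), a call lost without aged control 1 or 2 (adjusted p up to 0.0631). Of 40 senescence-associated secretory factors 3 rose (11 rose and 1 fell adjusted over the list alone), among them Igfbp3 and the protease nexin gene Serpine2, which lost its call without young control 1 or 2, each aged control or treated replicate 2 (adjusted p up to 0.175). The list had a median of 0.26 (adjusted p = 0.00489, and adjusted p = 0.71 with an estimated correlation). Igfbp3, an insulin-like growth factor carrier gene, went from 46.9 ± 5.81 to 105 ± 20.4 CPM and lost its call without aged control 2 (adjusted p = 0.0542). Cdkn1a, the gene of the cell cycle inhibitor p21, stood at 3.94 ± 0.645 CPM in aged control and 11.3 ± 5.48 CPM in treated samples (1.52 ± 0.34, adjusted p = 0.0398). The call was kept only without treated replicate 3 among the 9 fits that leave out 1 library (adjusted p up to 0.168). The Bruch membrane and extracellular matrix list had 5 of 26 members risen (9 adjusted over the list alone; median 0.14, adjusted p = 0.0336, and adjusted p = 0.41 with an estimated correlation). The call was lost without aged control 2 or treated replicate 1 or 3 (adjusted p up to 0.115), and the median was 0.06 without treated replicate 1. The epithelial-mesenchymal transition list had 3 of 22 risen (4 adjusted over the list alone; median 0.19, adjusted p = 0.0215, and adjusted p = 0.71 with an estimated correlation). The median was 0.12 without aged control 2 and 0.05 without treated replicate 2, where the call was lost (adjusted p = 0.116). The photoreceptor phagocytosis list had a median of 0.29 with 14 of its 15 members above 0 (adjusted p = 0.00862, and adjusted p = 0.36 with an estimated correlation). When adjusted over the list alone 3 members rose, and without treated replicate 1 its median was 0.18. With 1 library left out, the count of risen secretory factors ranged from 0 without aged control 2 to 14 without treated replicate 3, and was 1 without young control 2 or aged control 1 or 3. The matrix count was 2 and 3 without young control 2 and 3, and 0, 0 and 1 without aged control 1, 2 and 3. The transition count was 1 without aged control 1 or 2 and 5 without treated replicate 3.

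With the preset correlation alone, the nuclear lists of oxidative phosphorylation passed the test below 0 with treatment and the mitochondrially encoded genes above 0. The mean over both nuclear lists differed by -0.19 with a 95% interval of -0.48 to 0.11, which holds 0. For complex I the median was -0.23 with 36 of 38 members below 0 (adjusted p = 0.000163, and adjusted p = 0.82 with an estimated correlation). Its member of smallest p, Ndufv3, went from 34.1 ± 1.31 to 24.9 ± 2.94 CPM (-0.46 ± 0.12, adjusted p = 0.0638). For complexes II to V the median was -0.16 (adjusted p = 0.0284, and adjusted p = 0.82 with an estimated correlation). The call was lost without aged control 2 or treated replicate 2 or 3, and without treated replicate 3 the median was -0.10 and the adjusted p 0.353. Of the 13 mitochondrially encoded protein genes ND6, a complex I subunit that overlaps ND5 on the other strand, rose (0.67 ± 0.11, adjusted p = 0.0188), also when adjusted over the list alone. It lost its call without any 1 of the aged controls (adjusted p up to 0.109). Their median was 0.22 (adjusted p = 0.017, and adjusted p = 0.71 with an estimated correlation), with the call lost without treated replicate 3 (adjusted p = 0.118). Rod photoreceptor markers moved with this group, with a median of 0.62 (adjusted p = 0.0215, and adjusted p = 0.82 with an estimated correlation). The call was lost without aged control 1 or treated replicate 3, and without the latter the median was 0.22 and the adjusted p 0.456. Without treated replicate 1 that median was 0.94. Rab38, a small GTPase gene of melanosome formation, fell from 128 ± 3.32 to 69.4 ± 8.73 CPM (-0.88 ± 0.10, adjusted p = 0.00409). The melanogenesis and melanosome list had 2 of 20 members fallen (3 fallen and 1 risen adjusted over the list alone; median -0.19, adjusted p = 0.0383, and adjusted p = 0.82 with an estimated correlation). The call was lost without aged control 1 or 2 or treated replicate 2 or 3 (adjusted p up to 0.26), and the median was -0.10 without treated replicate 2. The count of fallen melanogenesis genes was 1 without any 1 of the young controls, the aged controls or treated replicate 2. Pon2, Rpe65 and Glb1 differed by -0.01 ± 0.08, 0.01 ± 0.13 and -0.11 ± 0.11, with adjusted p of 0.928, 0.981 and 0.569. The adjusted p of Hmox1, C3, Ppargc1a and Gfap were 0.117, 0.424, 0.266 and 0.785, and Cdkn2a had 5 to 23 counts per treated library. The other 31 lists had adjusted p from 0.057 to 0.949.

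**Figure D3:**
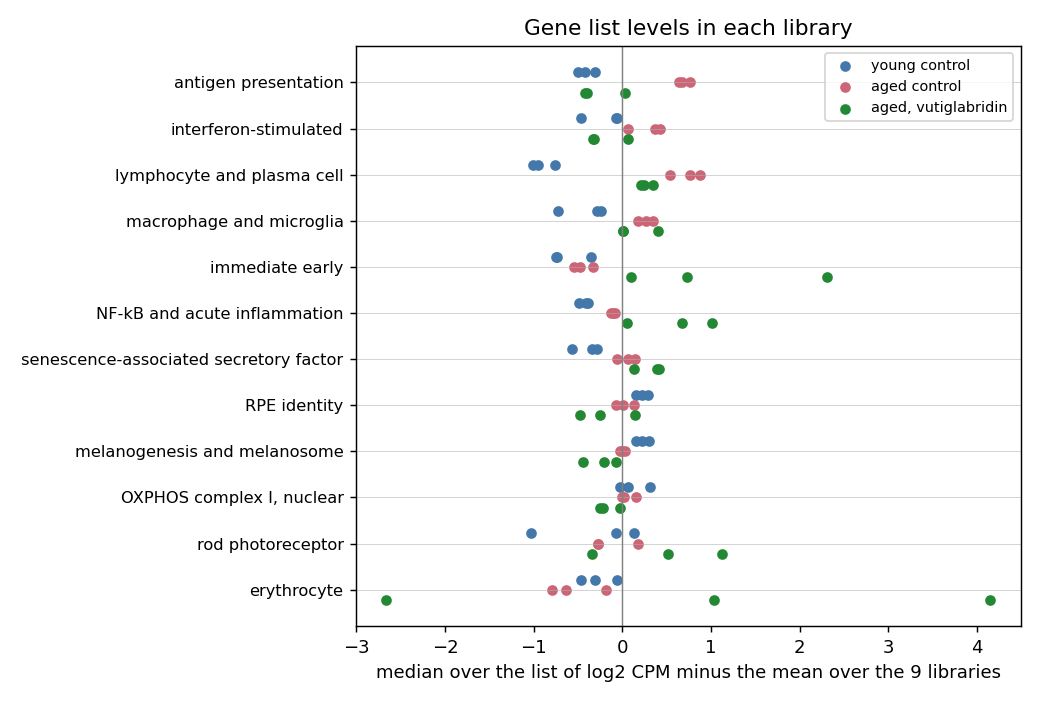
Medians of 12 gene lists in each library, as log2 CPM of each gene minus its mean over the 9 libraries; each point is a library, coloured by group (n = 3 per group). The antigen presentation median is highest in the aged controls, and that of rod photoreceptor genes reaches 1.13 in treated replicate 3.

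In all, 1098 of 25273 genes were called with treatment, 599 higher and 499 lower. An unadjusted p under 0.05 was seen for 6246 genes. The fit shares 1 estimate of the spread over the 3 groups, but their spread was unequal. The mean correlation of a library with its own group was 0.99 to 0.992 in aged controls. It was 0.977 to 0.984 in young controls and 0.974 to 0.977 in treated samples, so the threshold may not hold for these 1098 calls. With only the 2 groups compared, 178 genes were called with treatment. With libraries scaled by total counts only, 481 were higher and 753 lower. The count was 35, 25 and 63 without aged control 1, 2 and 3, 345 and 617 without young control 2 and 3, and 634, 561 and 4092 without treated replicate 1, 2 and 3. Of the 51 named genes called, 14, 11 and 21 kept their call without aged control 1, 2 and 3, 43, 27 and 34 without young control 1, 2 and 3, and 29, 32 and 51 without treated replicate 1, 2 and 3.

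Genes that differed with age were set against those that differed with treatment. Of the genes called in both, 78 were higher with age and lower with treatment, where 7.36 would be shared by independent lists, and 71 of these were not called between treated aged and young samples. Of all 373 genes higher with age 252 were still called higher in treated aged than in young samples, and of the 51 lower ones 42 were still called lower. These 2 contrasts use the same young control libraries, which adds to the overlap, and no expected count was computed. Among the genes called in opposite directions with age and treatment, 5 had the smallest treatment p. They were the interferon-inducible GTPase genes Tgtp1, Tgtp2, Irgm2 and Gvin3, and Gm42074, a predicted gene that overlaps Tgtp1. Irgm2 stood at 21.2 ± 1.18 CPM in young, 75 ± 14.3 in aged control and 22.2 ± 4.06 in treated samples, and Gvin3 at 13.0 ± 1.67, 31.0 ± 2.95 and 9.78 ± 1.82 CPM. Tgtp1, at 22.3 ± 3.37, 104 ± 19.0 and 25.5 ± 2.23 CPM, and Tgtp2 are near-identical copies, so the share of reads from each is uncertain. The genes Rgcc and Prex2, outside the rule for named genes, were the 2 called lower with age and higher with treatment, where 1.21 would be shared by independent lists. A further 17 genes were higher in both comparisons (8.84 by independent lists) and 5 lower in both (1.01). Both comparisons use the same aged control libraries. In 25 simulated draws with the fitted age effects and no treatment effect, at most 2 genes were called in opposite directions, against 80 observed, and in 25 draws with no effects at most 0 were. A median of 0 genes was called with treatment in these draws, against 1098 observed, so they leave out what shared controls add where treatment effects exist. Over all tested genes the covariance of the age and treatment log2 fold changes was -0.0116, against a simulated mean of -0.0589 (SD 0.00261) with age effects and no treatment effect, and the correlation across genes, which are not independent replicates, was -0.0461 against -0.301. The draws with no effects gave a mean covariance of -0.0576, so the simulated value comes mostly from noise in the shared aged controls. The draws gave each gene the same spread in all groups, while the real aged controls were the group most alike among themselves. The simulated covariance may therefore be too far below 0, and this comparison does not decide. The draws also called a median of 1179 genes with age, against 424 observed, and do not match the data in this. Genes higher with age had a median treatment log2 fold change of -0.242, and genes lower with age -0.127. The 3 aged controls cannot be split into groups of at least 2, so part of the excess of opposite calls may come from the shared controls. The 80 opposite calls were 53, 44 and 24 without young control 1, 2 and 3, 13, 12 and 24 without aged control 1, 2 and 3, and 149 without treated replicate 3. Those 149 were 132 higher with age and lower with treatment and 17 the other way. Without any 1 of the aged controls 0 went the other way by edgeR. DESeq2 split its 199 opposite calls into 169 and 30, and limma-voom its 324 into 239 and 85.

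**Figure D4:**
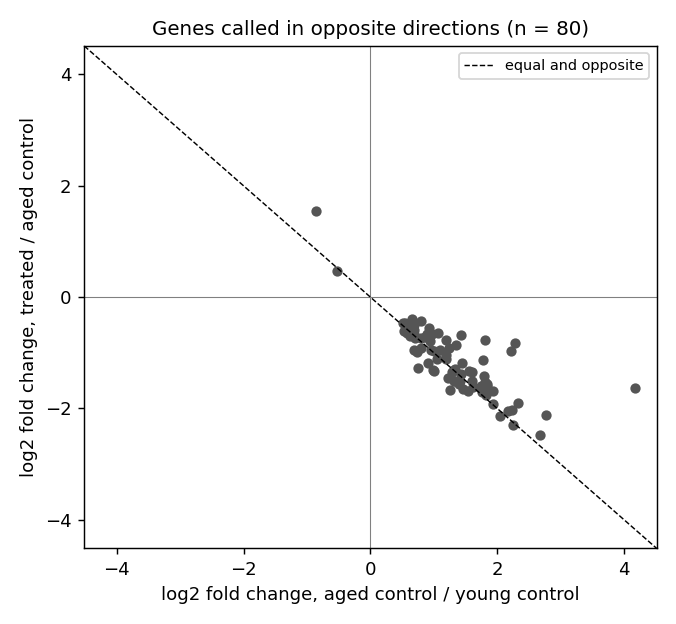
Log2 fold change with treatment (y axis) against that with age (x axis) for the 80 genes called in opposite directions; each point is a gene. Of these, 78 are higher with age and lower with treatment and 2 are lower with age and higher with treatment.

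The third comparison asked which differences from young RPE are present in treated aged animals. The median of antigen presentation genes was 0.04 (adjusted p = 0.192), but 5 of 20 were higher, also when adjusted over the list alone. Nlrc5 stood at 18.3 ± 2.19 CPM in young and 37.4 ± 5.36 CPM in treated samples (1.03 ± 0.13, adjusted p = 0.00239), and H2-Q7, H2-Q9 and H2-Q4 had log2 fold changes of 1.26, 1.46 and 0.75. Part of the immune cell and complement genes and most acute inflammation genes stood above young levels. Stat3, a transcription factor of cytokine signalling, stood at 104 ± 2.43 CPM in young and 238 ± 70.4 CPM in treated samples (1.20 ± 0.18, adjusted p = 0.00404), and C3 at 15.7 ± 3.59 and 60.7 ± 31.3 CPM (1.95 ± 0.33, adjusted p = 0.00843). Cdkn1a rose from 2.39 ± 0.219 to 11.3 ± 5.48 CPM (2.24 ± 0.35, adjusted p = 0.00517), and Hmox1, the stress-inducible haem oxygenase gene, from 11.5 ± 1.71 to 21.7 ± 5.13 CPM (0.92 ± 0.18, adjusted p = 0.0102). Fn1 rose from 109 ± 12.9 to 476 ± 116 CPM (2.13 ± 0.16, adjusted p = 0.000244) and Ccn2 from 221 ± 12.3 to 732 ± 136 CPM (1.73 ± 0.13, adjusted p = 0.0003).

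Of 40 senescence-associated secretory factors 22 rose (25 adjusted over the list alone), with a median of 0.74 (adjusted p = 1.92e-08, and adjusted p = 0.50 with an estimated correlation). Cxcl16 and the adhesion molecule gene Icam1 had 1.34 ± 0.14 and 0.93 ± 0.11. Of 22 NF-kB and acute inflammation genes 18 rose and 1 fell, also when adjusted over the list alone (median 1.07, adjusted p = 4.18e-07, and adjusted p = 0.55 with an estimated correlation). Of 19 immediate early genes 11 rose (17 adjusted over the list alone), with a median of 2.04 (adjusted p = 1.79e-06, and adjusted p = 0.63 with an estimated correlation) that was 1.01 without treated replicate 2. Of 24 complement genes 9 rose, also when adjusted over the list alone (median 0.47, adjusted p = 0.00711, and adjusted p = 0.63 with an estimated correlation). Of 20 macrophage and microglia markers 9 rose (11 adjusted over the list alone; median 0.67, adjusted p = 0.000391, and adjusted p = 0.63 with an estimated correlation). Of 22 epithelial-mesenchymal transition genes 8 rose (9 adjusted over the list alone; median 0.32, adjusted p = 0.00227, and adjusted p = 0.55 with an estimated correlation). Without treated replicate 2 these 3 medians were 0.25, 0.39 and 0.17. The secretory factor count was 14, 12 and 12 without young control 1, 2 and 3, and 13 and 14 without aged control 1 and 3. The NF-kB count was 8, 7 and 9 without young control 1, 2 and 3 and 11 without treated replicate 2. The immediate early count was 1, 0 and 4 without young control 1, 2 and 3 and 3, 4 and 5 without aged control 1, 2 and 3. The complement count was 3 and 5 without young control 1 and 3, and the transition count 5 without young control 2 or any 1 of the aged controls. Of 17 lymphocyte markers 9 rose and 2 fell (10 and 3 adjusted over the list alone; median 1.36, adjusted p = 0.00324, and adjusted p = 0.53 with an estimated correlation). The lymphocyte count was 5 without young control 1 or 2 for risen markers, and 0 to 2 for fallen ones over the libraries left out. Of 15 photoreceptor phagocytosis genes 6 rose (10 adjusted over the list alone; median 0.35, adjusted p = 0.00126, and adjusted p = 0.33 with an estimated correlation). Mfge8, which bridges outer segments to the RPE integrin receptor, rose from 70.1 ± 10.9 to 234 ± 65.2 CPM, and Gas6, a ligand of the receptor Mertk, from 170 ± 15.3 to 286 ± 53.9 CPM.

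Part of the RPE, pigment, nuclear OXPHOS and fatty acid oxidation genes were lower than in young samples. Rab38 fell from 143 ± 5.45 to 69.4 ± 8.73 CPM (-1.05 ± 0.10, adjusted p = 0.000604) and Pmel, the fibril protein gene of melanosomes, from 1170 ± 45.8 to 729 ± 63.1 CPM (-0.68 ± 0.09, adjusted p = 0.00289). Slco1c1, a thyroid hormone transporter gene, fell from 221 ± 57.2 to 62.7 ± 6.41 CPM (-1.82 ± 0.20, adjusted p = 0.00147). Of 20 melanogenesis and melanosome genes 11 fell and 2 rose (13 and 3 adjusted over the list alone), with a median of -0.51 (adjusted p = 0.000391, and adjusted p = 0.63 with an estimated correlation). Of 26 RPE identity genes 6 fell and 1, Best1, rose (9 and 1 adjusted over the list alone; Best1 lost its call without young control 1 or 2, adjusted p up to 0.0642), with a median of -0.36 (adjusted p = 0.00227, and adjusted p = 0.70 with an estimated correlation). Without treated replicate 2 these medians were -0.32 and -0.23, and without treated replicate 1 the RPE identity median was -0.56. The count of fallen RPE identity genes was 0 by edgeR without young control 1 or 2, 13 and 2 without treated replicate 1 and 2, and 3 without any 1 of the other libraries. That of melanogenesis genes was 7 without young control 1, treated replicate 2 or any 1 of the aged controls. Of 9 choroidal melanocyte genes 3 fell (6 adjusted over the list alone; median -0.39, adjusted p = 0.00227, and adjusted p = 0.55 with an estimated correlation). The choroidal melanocyte count ranged from 1 to 6 with 1 library left out. For complex I, 6 of 38 nuclear genes fell (8 adjusted over the list alone), with a median of -0.31 (adjusted p = 3.63e-06, and adjusted p = 0.70 with an estimated correlation). Ndufv3 went from 38.5 ± 5.99 to 24.9 ± 2.94 CPM (-0.63 ± 0.12, adjusted p = 0.0108). The count of 6 was 1 without young control 1 or 2, treated replicate 2 or 3 or any 1 of the aged controls, and 5 and 7 without treated replicate 1 and young control 3. The median of complexes II to V was -0.25, with Cox8a fallen over all genes but not when adjusted over the list alone (adjusted p = 0.00152, and adjusted p = 0.70 with an estimated correlation). That of mitochondrially encoded genes was 0.43, with 5 of 13 risen (8 adjusted over the list alone; adjusted p = 0.00178, and adjusted p = 0.55 with an estimated correlation). Without young control 1, which has the lowest mitochondrial share, these 3 medians were -0.21, -0.12 and 0.27. Cox8a kept its call only without young control 3 among the 9 fits that leave out 1 library (adjusted p up to 0.118). The count of risen mitochondrially encoded genes was 2 without treated replicate 1 or any 1 of the aged controls and 3 without young control 1 or 2 or treated replicate 3. Of 23 fatty acid oxidation genes 5 fell (6 adjusted over the list alone), among them Decr1, from 70.0 ± 6.99 to 44.3 ± 5.39 CPM. The median was -0.23 (adjusted p = 0.00551, and adjusted p = 0.70 with an estimated correlation). The call was lost without treated replicate 3 (median -0.15, adjusted p = 0.201). The count of fallen fatty acid oxidation genes was 1, 3 and 3 without young control 1, 2 and 3, 7 without treated replicate 1, and 2 without any 1 of the others. Other metabolic lists did not pass. Of 21 TCA cycle genes 3 fell (2 adjusted over the list alone; adjusted p = 0.0677), of 18 glycolysis genes 3 rose (4 risen and 1 fallen adjusted over the list alone; adjusted p = 0.342), and of 31 cholesterol and lipid genes 6 rose, also when adjusted over the list alone (adjusted p = 0.166). These 3 counts ranged from 0 to 4, 2 to 6 and 2 to 10 with 1 library left out. Rpe65, Gfap, Pon2, Ppargc1a and Glb1 had adjusted p of 0.0719, 0.82, 0.606, 0.891 and 0.976.

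Markers of other tissue differed from young levels in both directions. Of 15 Muller glia and astrocyte genes 6 fell, also when adjusted over the list alone (median -0.21, adjusted p = 0.0541), and of 17 endothelium genes 6 fell and 1 rose, also when adjusted over the list alone (median -0.12, adjusted p = 0.113). Of 10 lens crystallin and 10 ciliary body genes 2 each fell, also when adjusted over the list alone (adjusted p = 0.146 and 0.145), and of 17 inner retinal neuron genes 4 rose (5 adjusted over the list alone; median 0.73, adjusted p = 0.0541). With 1 library left out, the fallen counts of these lists ranged from 3 to 6 for Muller glia and astrocyte, 2 to 5 for endothelium, and 0 to 3 for lens crystallin and for ciliary body genes, and the risen count of inner retinal neuron genes from 1 to 5. The rod list had a median of 0.99, with Reep6 risen and Rom1 fallen over all genes but neither when adjusted over the list alone (adjusted p = 0.0126, and adjusted p = 0.70 with an estimated correlation). This call was lost without young control 2 (median 0.61) or treated replicate 3 (median 0.52, adjusted p = 0.221). Reep6 lost its call without young control 1 or 2 (adjusted p up to 0.0932), and Rom1 kept its call only without young control 3 (adjusted p up to 0.0923). The skeletal muscle list had a median of 1.22 (adjusted p = 0.00299, and adjusted p = 0.70 with an estimated correlation). That call was lost without young control 2 or treated replicate 2 (adjusted p up to 0.0775; median 0.65 without the latter). The matrix list, with 8 of 26 risen and 1 fallen (9 and 2 adjusted over the list alone), had a median of 0.16 (adjusted p = 0.0343, and adjusted p = 0.50 with an estimated correlation). It lost its call without young control 2 or treated replicate 1 (adjusted p up to 0.112). The autophagy and lysosome list, with 6 of 36 risen, also when adjusted over the list alone, had a median of 0.12 (adjusted p = 0.0497, and adjusted p = 0.70 with an estimated correlation). It kept its call only without young control 1 or 2 or treated replicate 3 (adjusted p up to 0.265). Its count of risen genes ranged from 3 to 8 with 1 library left out. The other 26 lists had adjusted p from 0.0515 to 0.97. In all, 4222 genes were called, 2278 higher and 1944 lower, and 8644 had an unadjusted p under 0.05. The count was 1806 and 1775 without young control 1 and 2, 2408, 2588 and 2641 without aged control 1, 2 and 3, and 2649 without treated replicate 2. Of the 85 named genes called, 57, 59 and 71 kept their call without young control 1, 2 and 3, 66, 68 and 70 without aged control 1, 2 and 3, and 76, 73 and 76 without treated replicate 1, 2 and 3.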

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

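The fit of 7 libraries without treated replicate 2 and young control 1, the fit of genes that overlap no other gene, and the haemoglobin and stratified epithelium covariates were chosen after seeing the data; the other alternatives were planned. The cause was not tested where a value below differs, unless fewer genes or fewer samples entered the fit. The main counts were 424 genes with age, 1098 with treatment, 4222 between treated aged and young, and 80 opposite calls. At an adjusted p under 0.10 they were 677, 3006 and 6911, and with a fold change of at least 1.5 the last count was 2618. DESeq2 called 930 genes with age and 3010 with treatment, with 199 opposite calls, and limma-voom 2078 and 2709, with 324. With only the 2 groups compared the counts were 1239, 178 and 1041, with 39 opposite calls. The main fit shares 1 estimate of the spread over all groups, although the aged controls were more alike among themselves than the treated or young libraries. The rod list as a covariate gave 2261 genes between treated aged and young and 50 opposite calls, and the 7 libraries gave 1794 and 128. Among genes that overlap no other, 613 were called with treatment and 2170 between treated aged and young. With the haemoglobin covariate 645 genes were called with treatment, and with the epithelium covariate 122. Counts under the other size factors, the other filters and with other cell types', abundant or mitochondrial genes left out were within 1.5 times the main counts. With treatment the counts by direction moved further than the totals. The CPM filter gave 1034 higher and 512 lower, total counts 481 and 753, and the rod covariate 443 and 304, against 599 and 499. The directions with age moved as well, against 373 higher and 51 lower in the main fit. They were 1348 and 730 with limma-voom, 932 and 307 with the 2 groups alone, and 748 and 182 with DESeq2. The 7 libraries gave 466 and 146, and genes that overlap no other 256 and 28. No setting of size factors moved the median of all genes by more than -0.057. Of 45 lists, 18 passed with age, 14 with treatment and 19 between treated aged and young; with an estimated correlation camera called 0 in each, with lowest adjusted p of 0.053, 0.36 and 0.33, and fry called 3, 2 and 12. Over the libraries left out in turn, the counts ranged from 73 to 688 with age, 25 to 4092 with treatment and 1775 to 6086 between treated aged and young, opposite calls from 12 to 149, and lists called from 15 to 20, 13 to 18 and 17 to 24.

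The replicate number gave little sign of pairing: 1 of 9 same-numbered pairs had a correlation of deviations from the group means above 0.1 (range -0.079 to 0.148). Pairs with different numbers ranged from -0.298 to 0.251, so this check cannot exclude that a number marks a shared litter or day. With the replicate block 317 genes were called with treatment and 51 in opposite directions, and 322 with age and 3587 between treated aged and young.

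Signs turned mainly for small differences that passed no test. The treatment difference of Pon2 was 0.005 with relative log expression size factors, 0.002 with DESeq2, 0.025 with limma-voom, 0.017 with the CPM filter, 0.004 with the 2 groups alone, 0.054 with the rod covariate, 0.000 among genes that overlap no other, 0.017 with the haemoglobin covariate and 0.058 with the epithelium covariate, and that of Glb1 with the last was 0.012. The treatment difference of Rpe65 was -0.055 with total counts, -0.002 without a filter and -0.003 with the replicate block. Between treated aged and young, Glb1 was 0.010 with relative log expression, 0.009 with DESeq2, 0.014 with the CPM filter, 0.097 with the rod covariate, 0.004 with other cell types' genes left out and 0.039 in the 7 libraries. In the same comparison Ppargc1a was -0.002 with total counts and -0.025 with the rod covariate, Pon2 0.035 and the rod list -0.066 with the rod covariate, and Gfap 0.317 in the 7 libraries. That value of the rod list is small by construction, since the covariate is the mean of the same list. In those 7 libraries the treatment difference of C3 was -0.059 and the age median of the complex I list 0.02. Leaving out 1 library turned the sign of the complex I list with age (-0.163 to 0.02), of Pon2 (-0.091 to 0.043), Rpe65 (-0.155 to 0.097), C3 (-0.056 to 0.707) and Gfap (-0.377 to 0.682) with treatment, and of Glb1 (-0.099 to 0.107), Ppargc1a (-0.044 to 0.086) and Pon2 (-0.132 to 0.001) between treated aged and young. That of Gfap treated aged versus young went from -0.861 to 0.198. Of the remaining values of single genes with 1 library left out, 1990 kept direction and side of the threshold, 496 lost their call and 44 gained one; under the other settings these numbers were 3447, 319 and 137. The 1990 and 3447 include genes that were not called in the main fit and stayed so. For lists, 415 kept both and 43 lost their call with 1 library left out, and 487 and 121 under the other settings. Depth limits low genes most: Cdkn2a had at most 23 counts in a library.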

Other observations

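The tests of macrophages, B cells, blood, epithelium, glucocorticoid signalling, RPE share and rod transcripts were chosen only after the result was seen; the simulation of the shared aged controls and the other splits of the samples were planned. The lists of glucocorticoid response, neutrophil and stratified epithelium genes, and the genes named with them, were chosen after values had been seen.

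Some genes that respond to glucocorticoids were higher in treated than in aged control samples: 9 of 20 measured members rose, and 17 when adjusted over the list alone; the count of 9 was 0, 0 and 1 by edgeR without aged control 1, 2 and 3, 5 without young control 2 or 3, and 17 without treated replicate 3. Fkbp5, the cochaperone of the glucocorticoid receptor, went from 52.2 ± 2.79 to 191 ± 68.5 CPM (SD, n = 3; log2 fold change 1.87 ± 0.25 SE, adjusted p = 0.0131 in edgeR), and Tsc22d3, the glucocorticoid-induced leucine zipper gene, from 53.1 ± 2.57 to 134 ± 42.6 CPM (1.33 ± 0.22, adjusted p = 0.0209). Per1, a clock gene that glucocorticoids also induce, went from 17.0 ± 1.36 to 71.9 ± 14.4 CPM (2.08 ± 0.27, adjusted p = 0.0108). The list had a median of 1.43 (camera p = 1.78e-11, and p = 0.0741 with an estimated correlation), against -0.17 with age (p = 0.138). Of its 20 genes 9 are also in another list. Of 18 circadian clock genes 4 rose and 1 fell with treatment (7 and 2 adjusted over the list alone; median 0.13, adjusted p = 0.057), and 0 rose by edgeR without any 1 of the aged controls.

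Keratin genes of stratified epithelium were uneven between libraries: Krt5 stood at 62.8 CPM in treated replicate 2, 13.0 in treated replicate 3, 5.43 in aged control 3 and under 0.2 CPM in the others. The stratified epithelium list, with 1 of 14 members risen, also when adjusted over the list alone, had a median of 3.20 with treatment (camera p = 0.000143, and p = 0.266 with an estimated correlation) and 2.17 with age (p = 0.0894). The neutrophil list, with 1 of 12 members risen and 1 fallen (2 and 1 adjusted over the list alone), had a median of 0.84 with treatment (p = 0.00815, and p = 0.175 with an estimated correlation) and 0.56 with age (p = 0.0157, and p = 0.21 with an estimated correlation). S100a8, an abundant neutrophil gene, was at 1.28 ± 0.0734 CPM in aged control and 2.28 ± 1.32 CPM in treated samples.

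Many antigen presentation genes and some interferon-inducible genes were lower in treated than in aged control samples. Fewer macrophages and microglia would lower their other genes as far, but the mean of that list differed by -0.11 (SE 0.18, 95% interval -0.54 to 0.33) against -1.01 (-1.32 to -0.69) for antigen presentation, which argues against them as the whole cause; 4 of its 20 genes are in another list and 19 reach 1 CPM in aged controls. Fewer B cells stay open, since the mean of 4 B cell genes differed by -1.74 (SE 0.39, -2.68 to -0.79), although Cd79a and Ms4a1 stood at 0.727 and 0.824 CPM in aged controls against 73.5 CPM for Gbp4. Sampling noise in the shared aged control libraries is argued against as the whole cause by the interval of -1.32 to -0.69, and the highest simulated count of opposite calls was 2 against 80 observed, although those draws had a median of 0 treatment calls and leave open how many opposite calls the shared controls add; a condition shared by the aged control animals, such as an infection, could produce the pattern and was not tested. A lower interferon response with treatment therefore remains a hypothesis, and Ifng itself, the gene of interferon gamma, was at 0.267 ± 0.107 CPM in aged control and 0.0853 ± 0.0703 CPM in treated samples (adjusted p = 0.21).

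The immediate early and acute inflammation lists had a higher mean level in treated than in aged control samples, with a difference of 1.15 (95% interval 0.21 to 2.09). This interval pools the spread of all 9 libraries and does not measure that of the treated group, which was wider. The immediate early medians were 0.73, 2.31 and 0.10 in treated replicates 1, 2 and 3. They were -0.54, -0.48 and -0.33 in aged controls 1, 2 and 3. More blood and stratified epithelium in the treated samples stay open: with the haemoglobin genes as a covariate the difference was 0.99 (-0.01 to 1.98), an interval that reaches 0, although the list medians were 1.32 (quartiles of members 0.75 and 1.87) and 0.63 (0.31 and 1.18) against 1.81 and 0.70 without it, and with the epithelium list it was 0.92 (-0.26 to 2.1), with medians of 1.19 (0.54 and 1.65) and 0.64 (0.32 and 1.18). Treated replicate 1, with the lowest haemoglobin share of the 9 libraries (0.004%) and Krt5 at 0.0465 CPM, had list medians of 0.73 and 0.67 against at most -0.33 and -0.08 in the aged controls, but 1 library does not decide. Glucocorticoid targets rose beside these lists, with a median of 1.15 and 13 above 0 among 14 members not displayed before their list was written (camera p = 6.7e-07, and p = 0.12 with an estimated correlation). These 14 are not an independent set, since 5 are also in another list and Tsc22d3 was named after values had been seen. With the 9 of them in no other list as a covariate the difference was 0.02 (-1.05 to 1.09), but a covariate that differs with the group can take up any difference between groups. Glucocorticoids repress genes such as Ptgs2, so this does not show a cause, and a trigger of both such as time of day, handling or stress at dissection may differ with the group and cannot be told apart from the treatment in these samples.

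Nuclear OXPHOS lists passed the test below 0 with treatment at the preset correlation, but the mean difference of -0.19 had a 95% interval of -0.48 to 0.11, which holds 0. A lower share of RPE cells would raise the markers of all other types alike only if other tissue entered in equal parts. The endothelium and Schwann cell lists moved apart by 0.33 (0.04 to 0.61, adjusted over the 10 pairs of 5 lists). Other tissue can enter in unequal parts, so this does not decide, and a lower RPE share stays open. The RPE identity list had a median of -0.17 with treatment, with 6 of 26 members above 0 (camera adjusted p = 0.131, and adjusted p = 0.82 with an estimated correlation). The Schwann cell list differed by -0.28 (-0.52 to -0.05) and the endothelium list by 0.04 (-0.15 to 0.23), while the other 9 pairs did not pass, the widest being rod against Schwann cell at 0.82 (-0.2 to 1.84). More rod transcripts may add to the pattern, and with the rod list as a covariate the difference was -0.16 (-0.53 to 0.21), which leaves this open. An effect of the treatment on mitochondrial genes is untested beside this.

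The 6 libraries of each comparison can be split 3 against 3 in 10 ways, too few for a share under 0.05. Every other split also holds libraries of both groups on each side. A difference between the groups then adds to the spread within each side and lowers the count of called genes. Low counts in the other splits are therefore no support for the real one. The real split gave 424 genes with age against at most 10 in another split, and 18 lists against 17, and only 1 of the 10 splits, the real one, gave as many genes or as many lists. For treatment it gave 1098 genes against 0 by edgeR in every other split (at most 2412 at an unadjusted p under 0.05), and 14 lists against 21, with 1 and 6 of the 10 splits as large, the real one included. Between treated aged and young it gave 4222 genes against 0 by edgeR (at most 2712 at an unadjusted p under 0.05), and 19 lists against 23, with 1 and 3 of the 10 splits as large, the real one included.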
